A study of Arabidopsis thaliana with 12 samples.

How the data were processed

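Poly-A RNA from developing Arabidopsis thaliana seeds was sequenced in 12 libraries, in 4 groups of 3. The groups were wild-type Col-0 in 2 separately named sets (Col-0-1 and Col-0-2), dellaq and lec1-4. Per the labels' protocols, plants grew at 22 °C with 16 h of light and 8 h of dark, seeds were taken out of siliques with a needle 9 days after pollination, and 3 µg of RNA per sample went into a library kit with poly-T bead selection, random priming and no step that marks strand. The labels define dellaq only by that name and do not say which DELLA genes it affects. They also do not say which wild-type set belongs to which mutant, nor that replicates were separate plants or harvests, so p-values measure the spread between these samples, which may be technical.

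The deposited values are FPKM per gene and library (fragments normalized per kilobase of transcript and per library size) as the authors computed them. The submitters' processing notes list Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0 without their roles. The genome build, the annotation, the counting mode and the treatment of reads that match several genes are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart, and near-identical copies (the RBCS small subunit genes, LHCB1 genes and the tandem SESA genes) may share reads, so their single values are uncertain. The files held 33602 gene IDs, of which 32835 matched a symbol table of the TAIR10.1 assembly. That table served for names, and the annotation and sequence of the same assembly for exon length and GC content per gene, although the authors' build is not stated. No coordinates are given. All 12 sample columns were mapped by name, with 0 unmapped columns.

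Counts were not used here, so depth was estimated from the steps between low FPKM values. Relative depth ranged from 0.925 to 1.31 times that of the first Col-0-1 library. With exon lengths of the symbol table's assembly, an inference, this corresponds to 13.7 M to 19.4 M fragments per library. FPKM sums were 685062 to 786547 per library, and 18505 to 19404 genes reached 1 FPKM. No pair of libraries held identical non-zero columns: the highest number of identical non-zero values between 2 libraries was 0.

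A count model had been planned. Because the values are FPKM, the planned fallback was used: limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), with 12 libraries in a single model, 1 mean per group, 8 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05 with no fold limit. All adjusted p-values for genes come from this test, which is two-sided. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Genes with at least 1 FPKM in at least 3 libraries were tested (20222 genes, leaving out 13380). That filter was chosen after the values were seen, because the planned one needs counts.

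The main comparisons set each mutant against the wild-type set listed beside it (dellaq against Col-0-1, lec1-4 against Col-0-2), and many results are also given against the other set. Several list results are given against the listed set only, and their counts can differ against the other. A gene is said to hold against both sets where it passed the threshold against each in the same direction. The wild-type sets were compared with each other, and the difference between the mutants' changes was tested as a contrast in the same model. Gene lists (22 lists, 385 genes, taken from textbook knowledge) were tested with camera at a preset correlation of 0.01 for lists with at least 5 tested members, beside camera with an estimated correlation and fry, with adjustment over the 22 lists. A list is said to be called where camera at the preset correlation passed, unless another test is named. Overlaps were set beside the overlap of independent lists and beside 20 simulations with no effect. The simulations set each mutant's mean midway between the wild-type sets and used only the spread within groups.

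Groups, comparisons, lists, the other settings to try and the rule for named genes were fixed before the data were examined. The rule names the 5 DELLA genes with LEC1, FUS3, ABI3 and LEC2; the 6 largest rises and falls that held against both sets, with a mean of at least 5 FPKM in the higher group (planned in CPM) and no overlap between the 3 mutant and 6 wild-type libraries; and up to 3 members with the smallest p of each list that was called or had at least 3 members past the threshold. It also names up to 4 genes per direction class shared by the mutants, and the 3 largest rises and 3 largest falls between the wild-type sets. Genes outside this rule are said to be chosen after their values were seen.

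The settings planned beside these were a fold limit of log2 1, no low-value filter, a filter of 5 FPKM, a pseudocount of 0.1, only the compared libraries, a replicate block, the other wild-type set, the mean of both sets, an estimated correlation in camera and leaving out each library. Median-ratio scaling, upper-quartile scaling, rescaling to equal FPKM sums, leaving out plastid, mitochondrial and rRNA genes, and removal of the length and GC trend (known for 20056 tested genes, 99.2%) were added after seeing the data.

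The test code was tested on simulated data of 20222 genes for dellaq against Col-0-1, with 100 genes changed at each of 2 sizes. It recovered 81% of genes changed by log2 0.5 and 94% of those changed by log2 1, with 7 false calls (3.85% of calls), and made 0 calls in a simulated comparison of unchanged Col-0-2 and Col-0-1. The changed genes were drawn from those with a mean log2(FPKM + 1) above 2, so recovery at lower levels was not measured. In simulated lec1-4 against Col-0-2 data, the shifted cell cycle list was the only 1 of 22 lists called. Genes were simulated as independent of each other, so this does not measure how often camera calls unshifted lists of correlated genes. Figures were drawn with Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9.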

Results

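Transcript levels were measured by poly-A RNA sequencing in developing Arabidopsis seeds at 9 days after pollination. The samples were 2 sets of wild-type Col-0 seeds (Col-0-1 and Col-0-2) and the mutants dellaq and lec1-4, with 3 libraries each. The series asks which genes depend on DELLA proteins, nuclear repressors of gibberellin responses, and on LEC1, a nuclear factor Y subunit that promotes embryo maturation. Levels are FPKM, given as mean ± SD with n = 3 libraries per group. Estimated depth was 13.7 M to 19.4 M fragments per library, and 18505 to 19404 genes reached 1 FPKM. Within a group, libraries correlated across genes at r = 0.987 to 0.993. The first principal component held 49.7% of the variance and the second 34.05%. Adjusted p-values for genes are from limma on log2(FPKM + 1), and log2 changes are on that scale, which understates changes of genes with low values. Where a pair of log2 changes is given for dellaq, it is against Col-0-1 and then Col-0-2; for lec1-4 it is against Col-0-2 and then Col-0-1, and paired adjusted p-values follow the same order.

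**Figure D1:**
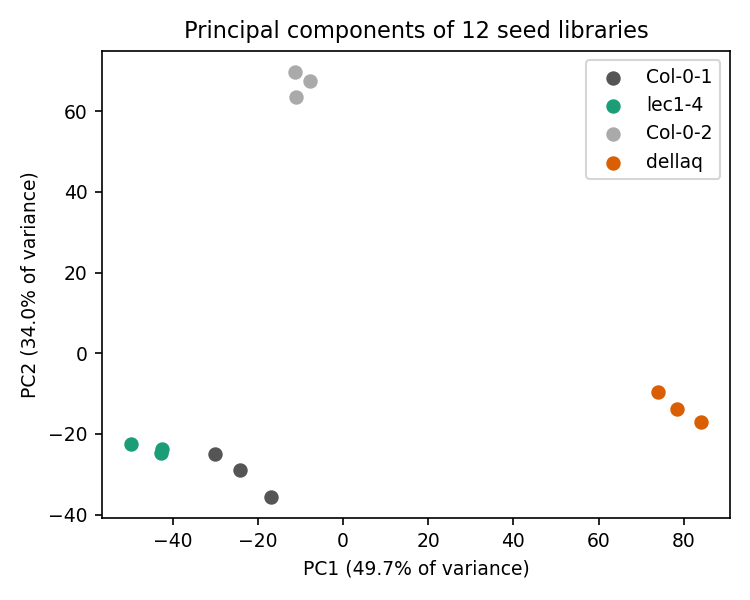
Principal components 1 (49.7% of variance) and 2 (34.05%) of log2(FPKM + 1) over the tested genes, with each point a library. The 3 libraries of each group lie together, and the Col-0-1 and lec1-4 libraries lie nearer to each other than either does to the Col-0-2 or dellaq libraries.

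The genes named by the genotypes were examined first. LEC1 (AT1G21970) measured 2.63, 2.38, 3.42 FPKM in the 3 lec1-4 libraries, against 124 ± 1.02 in Col-0-2 and 80.5 ± 12.9 in Col-0-1 (log2 changes of -5.04 and -4.42, adjusted p = 1.3e-08 and 2.5e-07). Of the 5 DELLA genes, 3 were lower in dellaq against both wild-type sets. RGL1 (AT1G66350) measured 1.51, 1.61, 1.05 FPKM in the dellaq libraries, against 14.4 ± 0.0977 in Col-0-1 and 9.28 ± 0.791 in Col-0-2 (log2 changes of -2.69 and -2.11, adjusted p = 6.5e-10 and 6.6e-09). RGL2 (AT3G03450) measured 3.74, 6.01, 4.22 FPKM, against 25.5 ± 0.528 and 16.9 ± 1.11 (log2 changes of -2.25 and -1.68, adjusted p = 1.0e-08 and 9.6e-08). RGA (AT2G01570) fell less far, to 20.8 ± 0.252 FPKM from 28.2 ± 1.11 and 25.6 ± 1.23 (log2 changes of -0.42 and -0.29, adjusted p = 1.2e-05 and 3.0e-04), with dellaq library values of 21.03, 20.5, 20.8. GAI (AT1G14920) averaged 8.98 ± 2.89 FPKM in dellaq (12.2, 6.63, 8.09 by library), against 8.88 ± 0.961 and 8.55 ± 0.327, and did not pass either test (adjusted p = 0.916 and 0.899). RGL3 (AT5G17490) averaged 8.00 ± 0.847 FPKM in dellaq (7.93, 7.19, 8.88 by library), against 6.55 ± 0.611 and 6.47 ± 0.593. The difference did not pass either test (log2 changes of 0.25 and 0.27, adjusted p = 0.0616 and 0.0526). Against Col-0-1 it passed with median-ratio (0.48, adjusted p = 0.00222) and upper-quartile scaling (0.38, adjusted p = 0.00802) and with the length and GC trend removed (0.45, adjusted p = 0.00354). It also passed without dellaq replicate 2 (0.32, adjusted p = 0.0391) or lec1-4 replicate 2 (0.25, adjusted p = 0.0363). In lec1-4, RGL1 and RGL2 were higher than in Col-0-2 (log2 changes of 0.60 and 0.74, adjusted p = 1.2e-04 and 9.6e-05) but not than in Col-0-1 (0.02 and 0.17, adjusted p = 0.917 and 0.291). Camera did not call the DELLA list in dellaq against Col-0-1 (3 of 5 lower, adjusted p = 0.291) or in lec1-4 against Col-0-2 (2 higher, adjusted p = 0.372). By fry the adjusted p was 4.5e-07 and 1.2e-04, and 0.217 in lec1-4 against Col-0-1. However, fry also called 18 lists between the wild-type sets. Transcript levels do not show which DELLA proteins were missing, and the labels do not name the mutated genes.

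**Figure D2:**
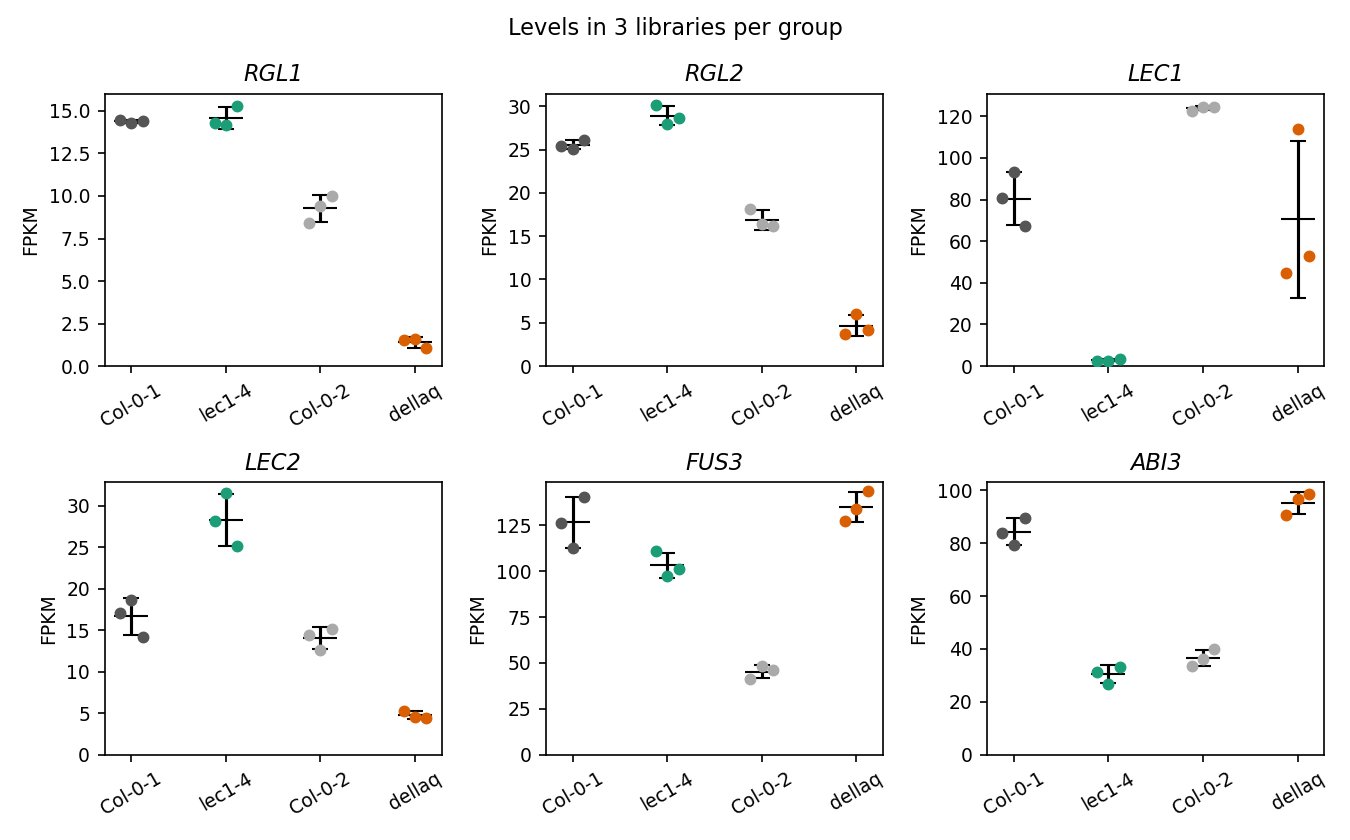
FPKM of RGL1, RGL2, LEC1, LEC2, FUS3 and ABI3 in each library (points), with the group mean and SD. RGL1, RGL2 and LEC2 lie lowest in dellaq, LEC1 lies lowest in lec1-4, and FUS3 and ABI3 differ between the wild-type sets.

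The wild-type sets, the same genotype sampled under separate names, gave the background for both mutant comparisons, and they differed widely. Col-0-2 seeds had lower levels of seed storage protein genes (11 of 13 lower, median log2 change -2.83), oil body genes (12 of 14, median -1.16) and nuclear photosynthesis genes (36 of 42, median -0.60) than Col-0-1 seeds. Wounding and touch genes were higher (9 of 9, median 1.15). The 2S albumin gene SESA2 (AT4G27150) averaged 15.7 ± 11.1 FPKM in Col-0-2 and 566 ± 409 in Col-0-1 (log2 change -5.01, adjusted p = 3.7e-05), although tandem copies such as SESA1 and SESA2 may share reads. The glycine-rich protein gene GRP5 (AT3G20470) rose to 909 ± 293 from 7.44 ± 0.393 FPKM (6.71, adjusted p = 7.3e-10). The master regulators of maturation FUS3 (AT3G26790) and ABI3 (AT3G24650) averaged 45.3 ± 3.54 and 36.6 ± 3.16 FPKM in Col-0-2 against 127 ± 13.8 and 84.3 ± 5.08 in Col-0-1 (log2 changes of -1.46 and -1.18, adjusted p = 2.3e-08 and 1.3e-07).

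Camera called 8 of 22 lists between the wild-type sets. Lower in Col-0-2 were seed regulators (15 of 20, adjusted p = 0.00138), storage proteins (adjusted p = 0.00849), oil body genes (0.00527), plastid fatty acid synthesis (17 of 27, 0.0458), photosynthesis (9.8e-08) and silique wall markers (8 of 10, 0.0458). Higher were seed coat flavonoid genes (11 of 15, adjusted p = 0.0267) and wounding and touch genes (0.00138). With an estimated correlation camera called 0 lists and 1 list had an unadjusted p under 0.05. The adjusted p with an estimated correlation was 0.352 for seed regulators and 0.579 for each of the other lists called. The fatty acid call ended with median-ratio (adjusted p = 0.254) and upper-quartile scaling (adjusted p = 0.191). The flavonoid call ended with median-ratio scaling (adjusted p = 0.0501) and the silique call with equal FPKM sums (adjusted p = 0.0817). Stomata and trichome genes were called downward with median-ratio (adjusted p = 0.039) and upper-quartile scaling (adjusted p = 0.0464).

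In all, 13320 of 20222 genes differed between the wild-type sets, 5210 higher and 8110 lower in Col-0-2. The other large falls were in AT3G41979, from 393 ± 78.0 to 5.46 ± 1.44 FPKM (log2 change -5.93), and AT5G05020, from 100.1 ± 61.6 to 1.81 ± 1.76 FPKM (-5.13). The largest rises were in the plastid-encoded genes ATCG00390 (0.615 ± 1.06 to 333 ± 20.3 FPKM, log2 change 7.88) and ATCG00220 (8.76 ± 4.90 to 1352 ± 76.9 FPKM, 7.24). The higher and lower calls moved to 6658 and 6275 with median-ratio scaling, 6447 and 6524 with upper-quartile scaling and 3893 and 10382 with equal FPKM sums.

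Library features divided the groups in the same way, with Col-0-1 and lec1-4 on a side and Col-0-2 and dellaq on the other. Plastid-encoded genes summed to 202 ± 42.9 FPKM in Col-0-1 and 164 ± 31.8 in lec1-4, against 4819 ± 266 in Col-0-2 and 7673 ± 803 in dellaq. Mitochondrial genes summed to 85.0 ± 16.1 and 98.2 ± 12.4 FPKM, against 195 ± 51.1 and 385 ± 70.3. Nuclear rRNA loci went the other way, at 1132 ± 241 and 1272 ± 147 FPKM against 56.7 ± 22.1 and 142 ± 37.1. Each gene's deviation from its mean over the 12 libraries was also set beside its length. Spearman's rho between them, across genes, was 0.287 and 0.244 against -0.227 and -0.164. Of 99 tested plastid-encoded genes, 93 were higher in dellaq than in Col-0-1 and 75 higher than in Col-0-2. In lec1-4, 76 were lower and 2 higher than in Col-0-2, against 5 lower and 2 higher than in Col-0-1. The comparisons within a side are therefore dellaq against Col-0-2 and lec1-4 against Col-0-1, which the labels do not name as pairs.

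**Figure D3:**
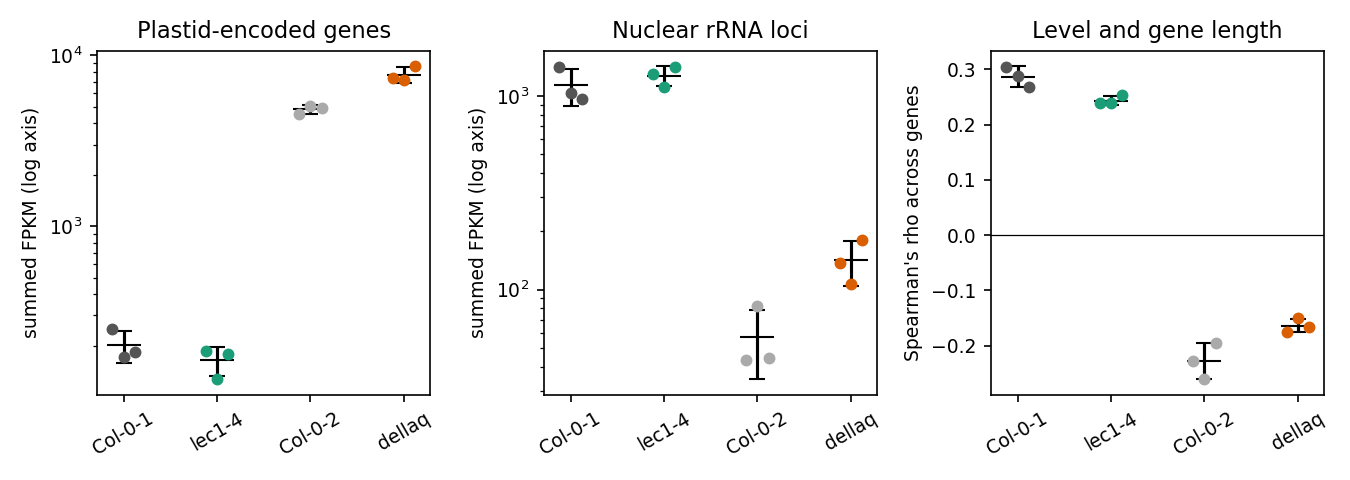
Summed FPKM of plastid-encoded genes and of nuclear rRNA loci (log axes) and Spearman's rho with gene length in each library (points), with the group mean (black dash) and SD (bar). The rho is between gene length and each gene's deviation from its mean over the 12 libraries. Plastid sums average 202 and 164 FPKM in Col-0-1 and lec1-4 and 4819 and 7673 FPKM in Col-0-2 and dellaq.

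Seeds of dellaq had higher levels of maturation genes and lower levels of cell cycle and seed coat genes than either wild-type set. All 13 tested storage protein genes, 12 of 14 oil body and oil assembly genes and 18 of 19 late embryogenesis abundant (LEA) and desiccation genes were higher against both sets. With the other scalings 13, 12 to 13 and 17 to 19 were, and 1 oil gene was lower with equal FPKM sums. The oleosin gene OLEO1 (AT4G25140), whose protein coats oil bodies, averaged 4673 ± 755 FPKM in dellaq against 765 ± 261 in Col-0-1 and 105 ± 21.4 in Col-0-2 (log2 changes of 2.65 and 5.47, adjusted p = 2.4e-05 and 6.0e-08). CA1 (AT3G01500), a plastid carbonic anhydrase, averaged 0.644 ± 0.122 FPKM in dellaq against 54.3 ± 2.18 in Col-0-1 and 20.3 ± 0.476 in Col-0-2 (log2 changes of -5.07 and -3.70, adjusted p = 8.5e-14 and 4.7e-12). The cyclin-dependent kinase gene CDKB1;2 (AT2G38620), active around mitosis, averaged 8.72 ± 0.396 FPKM in dellaq against 17.1 ± 0.703 in Col-0-1 and 17.8 ± 1.75 in Col-0-2 (log2 changes of -0.90 and -0.95, adjusted p = 3.0e-07 and 1.9e-07).

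Against Col-0-1, 14218 of 20222 genes differed in dellaq, 3917 higher and 10301 lower, and 2329 of them by at least a log2 change of 1. Against Col-0-2 there were 12843 (4424 higher, 8419 lower). Calls held against both sets for 7716 genes, 1978 higher and 5738 lower, while 1930 genes passed against both sets in opposite directions. Simulations without effects gave 4.5 held calls on average, but they set each mutant midway between the wild-type sets. They leave out differences between sets of the same genotype and so do not measure that background. Where the wild-type sets differ, a mutant mean midway gives changes of opposite sign against them, so few held calls could arise. The median change of all genes was -0.22 against Col-0-1 and -0.12 against Col-0-2. Median-ratio scaling moved these to 0.0014 and -0.0023 and the held calls to 3511 higher and 3274 lower. Upper-quartile scaling moved the medians to -0.10 and -0.09 and the held calls to 2580 and 4397, and equal FPKM sums to -0.39 and -0.15 and to 1409 and 7080. With median-ratio scaling the excess of lower over higher calls thus turned for the held calls and against Col-0-1 (6531 higher and 6041 lower), while against Col-0-2 it shrank to 6163 and 6300. Upper-quartile scaling gave 5267 and 7756 against Col-0-1 and equal sums 2674 and 12980.

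Storage protein genes rose as a group (median log2 change 3.60 against Col-0-1, camera adjusted p = 4.7e-09, and adjusted p = 0.443 with an estimated correlation). The 12S globulin gene CRC (AT4G28520) averaged 2908 ± 1341 FPKM in dellaq against 75.2 ± 71.4 in Col-0-1 and 1.94 ± 1.41 in Col-0-2 (log2 changes of 5.91 and 9.98, adjusted p = 1.6e-04 and 2.3e-06), with dellaq library values of 1623, 4299, 2799.9. SESA5 (AT5G54740), a 2S albumin, averaged 340.5 ± 133 FPKM in dellaq (log2 changes of 4.26 and 7.09). CRD (AT1G03890), another globulin gene, reached 78.8 ± 42.9 FPKM from 0.251 ± 0.184 and 0.162 ± 0.0744. The vicilin-like gene AT4G36700 reached 918 ± 74.1 from 354 ± 30.7 and 318 ± 12.8 (log2 changes of 1.37 and 1.52). Oil body and oil assembly genes rose as well (12 of 14, median 1.82, adjusted p = 5.9e-09, and adjusted p = 0.343 with an estimated correlation). Oleosin genes OLEO2 (AT5G40420) and OLEO3 (AT5G51210) averaged 2471 ± 368 and 2354 ± 149 FPKM against 393 ± 91.6 and 1028 ± 98.8 in Col-0-1. The caleosin gene CLO1 (AT4G26740) averaged 390.2 ± 98.0 against 28.9 ± 15.0. LEA and desiccation genes rose in 19 of 19 cases (median 2.78, adjusted p = 2.4e-11, and adjusted p = 0.343 with an estimated correlation). LEA7 (AT1G52690) averaged 131 ± 40.0 FPKM in dellaq against 14.0 ± 2.49 in Col-0-1 and 3.88 ± 1.39 in Col-0-2 (log2 changes of 3.10 and 4.74, adjusted p = 6.3e-07 and 2.2e-08). AT3G17520 reached 36.5 ± 16.2 FPKM from 0.518 ± 0.313 and 0.427 ± 0.155. Genes of plastid fatty acid synthesis had a smaller median change (21 higher and 2 lower of 27, median 0.36, adjusted p = 9.6e-10, and adjusted p = 0.343 with an estimated correlation). Against both sets 21 were higher, or 14 higher and 1 lower with equal FPKM sums. EMB3003 (AT1G34430), a pyruvate dehydrogenase subunit, averaged 307 ± 18.4 FPKM in dellaq against 201 ± 5.43 in Col-0-1 and 219 ± 4.86 in Col-0-2 (log2 changes of 0.61 and 0.48, adjusted p = 2.6e-07 and 1.8e-06). Enoyl reductase MOD1 (AT2G05990) averaged 506 ± 21.6 FPKM against 351 ± 0.765 and 356 ± 11.7 (log2 changes of 0.53 and 0.51).

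Seed regulators moved in both directions (7 higher and 7 lower of 20 against Col-0-1, not called, adjusted p = 0.254, with the list's median turning from 0.10 to -0.08 with equal FPKM sums). Against both sets, 7 were higher and 4 lower, or 11 and 3 with median-ratio scaling, 11 and 4 with upper-quartile scaling and 6 and 5 with equal FPKM sums. LEC2 (AT1G28300), a B3 domain activator of maturation, fell to 4.74 ± 0.464 FPKM from 16.7 ± 2.26 and 14.0 ± 1.31 (log2 changes of -1.62 and -1.39, adjusted p = 1.1e-07 and 3.7e-07). BZIP67 (AT3G44460), a basic leucine zipper activator of maturation genes, rose (log2 changes of 1.49 and 2.64), as did the dormancy gene DOG1 (AT5G45830) (2.68 and 1.96). FUS3 averaged 135 ± 8.07 FPKM and did not pass the test against Col-0-1 (log2 change 0.09, adjusted p = 0.317), but was above Col-0-2 (1.55, adjusted p = 1.7e-08). Against Col-0-1 it passed with median-ratio (0.35, adjusted p = 0.00331) and upper-quartile scaling (0.24, adjusted p = 0.0205) and with the length and GC trend removed (0.32, adjusted p = 0.00382). ABI3, at 95.3 ± 4.24 FPKM, behaved likewise (0.18, adjusted p = 0.0713, against 1.36, adjusted p = 4.0e-08), but several settings made it pass against Col-0-1. Among these were median-ratio (log2 change 0.43, adjusted p = 0.00063) and upper-quartile scaling (0.32, adjusted p = 0.00364), removal of the length and GC trend (0.51, adjusted p = 1.5e-04) and a fit of only the compared libraries (0.18, adjusted p = 0.025). Others were leaving out Col-0-1 replicate 3 (0.22, adjusted p = 0.0489) or lec1-4 replicate 2 (0.18, adjusted p = 0.0338). LEC1 itself spread widely in dellaq, at 44.6, 114, 53.1 FPKM. It did not pass against Col-0-1 (log2 change -0.30, adjusted p = 0.317) unless dellaq replicate 2 was left out (-0.70, adjusted p = 0.00071), and was below Col-0-2 (-0.93, adjusted p = 0.00761). BZIP53 (AT3G62420) was listed at 0 in all 12 libraries and was not tested.

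**Figure D4:**
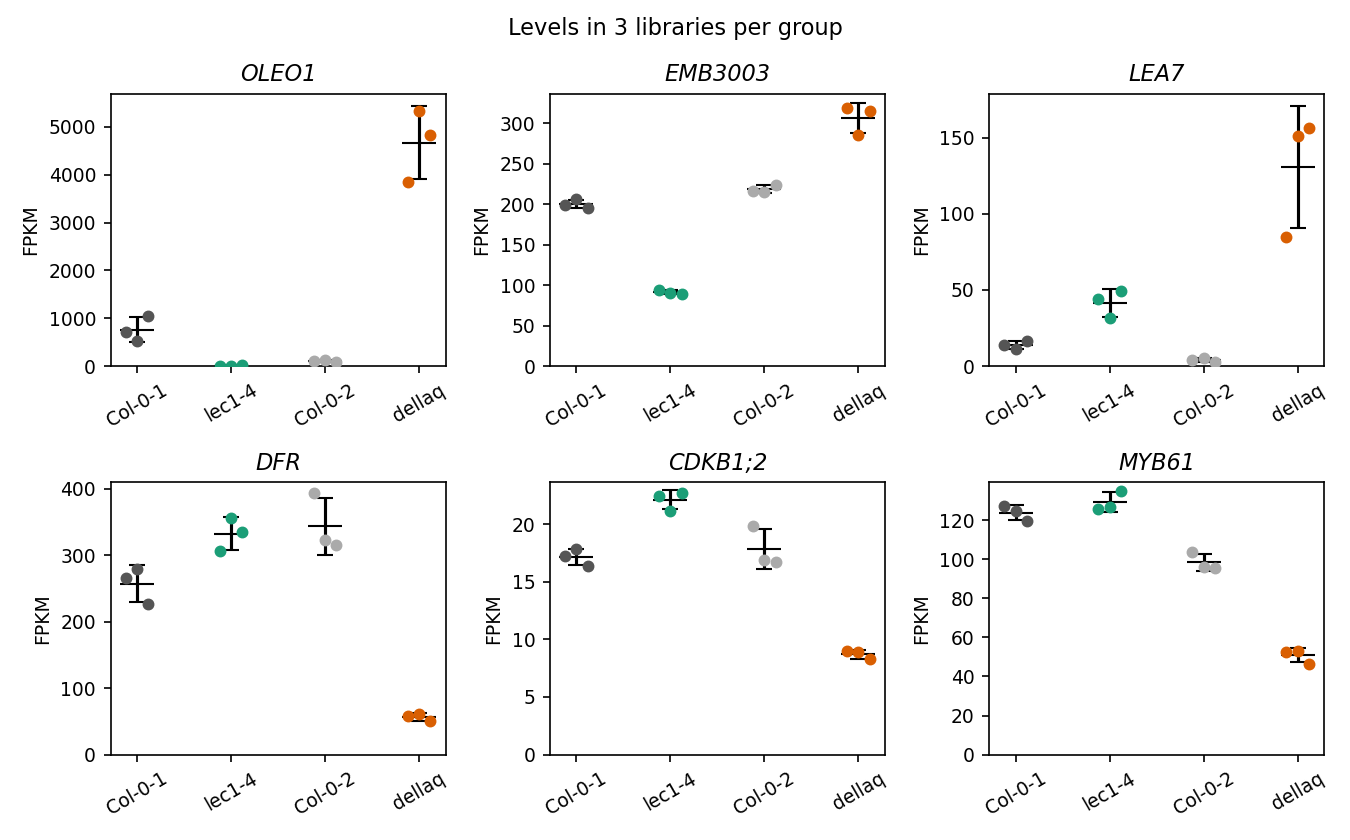
FPKM of OLEO1, EMB3003, LEA7, DFR, CDKB1;2 and MYB61 in each library (points), with the group mean and SD. OLEO1, EMB3003 and LEA7 are highest in dellaq, and DFR, CDKB1;2 and MYB61 are lowest there; EMB3003 is lowest and LEA7 above both wild-type sets in lec1-4.

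Cell cycle genes were lower in dellaq in 25 of 25 cases against Col-0-1 (median -0.64, adjusted p = 5.3e-05, and adjusted p = 0.443 with an estimated correlation). Against both sets 23 of 25 were lower, or 14 with median-ratio scaling and 20 with upper-quartile scaling. The replication licensing gene MCM2 (AT1G44900) averaged 13.6 ± 1.099 FPKM against 25.02 ± 1.78 and 24.0 ± 0.216 (log2 changes of -0.83 and -0.77). The spindle factor TPX2 (AT1G03780) averaged 17.56 ± 0.927 against 34.9 ± 0.723 and 20.5 ± 0.694. Seed coat flavonoid genes, which make the brown tannins of the coat, were lower in 14 of 15 cases (13 against both sets, median -1.21, adjusted p = 4.6e-04, and adjusted p = 0.45 with an estimated correlation). The dihydroflavonol reductase gene DFR (AT5G42800) averaged 56.5 ± 5.98 FPKM in dellaq against 257 ± 27.2 in Col-0-1 and 344 ± 42.8 in Col-0-2 (log2 changes of -2.17 and -2.58, adjusted p = 7.0e-09 and 3.6e-09). The glutathione transferase gene TT19 (AT5G17220) averaged 15.1 ± 3.47 FPKM in dellaq against 148 ± 19.2 in Col-0-1 and 197 ± 28.1 in Col-0-2 (log2 changes of -3.22 and -3.63, adjusted p = 3.9e-09 and 3.6e-09). Seed coat mucilage genes were lower in 17 and higher in 1 of 24 cases (median -0.60, adjusted p = 0.034, and adjusted p = 0.647 with an estimated correlation). Against both sets 16 were lower, or 13 lower and 3 higher with median-ratio scaling. Among them, the transcription factor genes MYB61 (AT1G09540) and GL2 (AT1G79840) averaged 50.8 ± 3.59 and 61.9 ± 7.69 FPKM, against 124 ± 3.96 and 187 ± 17.36 in Col-0-1 and 98.4 ± 4.52 and 139 ± 7.63 in Col-0-2. Silique wall and replum markers, from the fruit tissue around the seeds, were lower in 9 of 10 cases against Col-0-1 (adjusted p = 0.034, and adjusted p = 0.443 with an estimated correlation; adjusted p = 0.0658 with equal FPKM sums) and in 5 against both sets. FUL (AT5G60910) averaged 2.23 ± 0.0278 FPKM against 15.5 ± 0.305 and 5.05 ± 1.74, and against Col-0-2 the list was not called (adjusted p = 0.837).

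Photosynthesis genes moved in both directions. Against both sets, 20 of 42 were higher and 5 lower, or 31 and 4 with median-ratio scaling and 14 and 5 with equal FPKM sums. The light-harvesting gene LHCB6 (AT1G15820) averaged 746 ± 21.5 FPKM against 399 ± 6.36 and 420.4 ± 21.8 (log2 changes of 0.90 and 0.83). The photosystem I gene PSAK (AT1G30380) averaged 550.4 ± 29.6 against 229 ± 8.53 and 280.4 ± 14.9. The Rubisco small subunit genes RBCS2B (AT5G38420) and RBCS3B (AT5G38410), near-identical copies, fell to 5.73 ± 0.142 and 76.0 ± 6.30 FPKM from 119 ± 11.02 and 344 ± 6.86 in Col-0-1. Camera called the list upward against Col-0-1 (20 higher and 9 lower, adjusted p = 7.3e-04, and adjusted p = 0.647 with an estimated correlation). Its median was 0.10, its mean -0.07, and its median -0.09 with equal FPKM sums. Plastid-encoded transcripts moved with the dellaq libraries here, at 7673 ± 803 FPKM against 202 ± 42.9 in Col-0-1.

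Of the hormone lists camera called none in dellaq against Col-0-1. By fry the adjusted p was 6.4e-07 for gibberellin synthesis and inactivation, 1.9e-06 for DELLA-induced targets and 0.00189 for auxin genes. It was 0.0115 for abscisic acid genes and 0.682 for GASA genes. Gibberellin synthesis and inactivation genes were lower in 10 and higher in 2 of 14 cases against Col-0-1 (adjusted p = 0.228), and lower in 5 and higher in 4 against Col-0-2 (adjusted p = 0.837). KAO2 (AT2G32440), an ent-kaurenoic acid oxidase, averaged 10.5 ± 0.940 FPKM against 31.5 ± 2.23 and 30.05 ± 2.81 (log2 changes of -1.51 and -1.44, adjusted p = 1.1e-08 and 1.8e-08). GA3OX1 (AT1G15550), which makes active gibberellin, fell against Col-0-1 (-1.62, adjusted p = 3.4e-06) but rose against Col-0-2 (0.89, adjusted p = 4.8e-04). DELLA-induced target genes, a list taken from work in other tissues, were lower in 10 of 12 cases against Col-0-1 (adjusted p = 0.177, or 0.046 with median-ratio scaling). Against both sets 8 were lower and 1 higher, or 5 and 2 with median-ratio scaling and 5 and 1 with upper-quartile scaling. BHLH137 (AT5G50915) averaged 3.14 ± 0.333 FPKM against 34.3 ± 1.80 and 20.8 ± 3.70 (log2 changes of -3.10 and -2.38). The gibberellin receptor gene GID1A (AT3G05120) averaged 11.9 ± 1.15 against 22.5 ± 1.404 and 22.5 ± 1.63 (-0.87 and -0.87). Of 5 gibberellin-induced GASA genes, 2 were higher and 1 lower (adjusted p = 0.488, median -0.12, mean 0.18, with a median of 0.13 with median-ratio scaling). GASA4 (AT5G15230) rose (log2 changes of 0.70 and 0.36), and GASA6 (AT1G74670) fell against Col-0-1 (-0.87) and rose against Col-0-2 (0.39). Auxin genes were higher in 5 and lower in 9 of 18 cases (median -0.24, camera upward, adjusted p = 0.794), with the auxin synthesis gene YUC10 (AT1G48910) at 28.3 ± 3.36 FPKM against 7.94 ± 1.48 and 6.36 ± 0.876. Abscisic acid genes were higher in 5 and lower in 8 of 20 (median -0.12, or 0.12 with median-ratio scaling, camera upward, adjusted p = 0.574). The phosphatase gene HAI1 (AT5G59220) reached 244 ± 19.9 FPKM from 105 ± 9.59 and 116 ± 3.32.

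The heat shock list was called against Col-0-1 (4 of 7 higher, adjusted p = 0.00821, and adjusted p = 0.45 with an estimated correlation; adjusted p = 0.0711 with median-ratio scaling), and not against Col-0-2 (adjusted p = 0.0829). The chaperone gene HSP70 (AT3G12580) averaged 51.0 ± 1.15 FPKM against 28.1 ± 1.16 and 30.9 ± 4.79. Endosperm markers were higher in 3 and lower in 7 of 14 cases against Col-0-1 (adjusted p = 0.961). Against Col-0-2 they were higher in 1 and lower in 10 (median -0.78, adjusted p = 0.0514, and adjusted p = 0.259 with an estimated correlation). There the list was called downward with median-ratio (adjusted p = 0.0162) and upper-quartile scaling (adjusted p = 0.0381). The endosperm transcription factor gene ZOU (AT1G49770) averaged 17.2 ± 3.28 FPKM against 37.0 ± 2.26 and 37.1 ± 2.25 (log2 changes of -1.08 and -1.08). Embryo patterning genes were higher in 3 and lower in 7 of 18 against Col-0-1 (median -0.17, or 0.03 with median-ratio scaling, camera upward, adjusted p = 0.896), and the homeobox gene WOX8 (AT5G45980) fell (log2 changes of -1.93 and -1.70). Stomata and trichome genes were higher in 3 and lower in 6 of 12 (median -0.28, camera upward, adjusted p = 0.859). The myrosinase gene TGG2 (AT5G25980) fell from 221 ± 15.2 to 6.33 ± 1.52 FPKM and the guard cell regulator MYB60 (AT1G08810) rose from 15.6 ± 2.096 to 62.0 ± 7.89. Jasmonate and defence genes were lower in 7 of 12 against Col-0-1 (adjusted p = 0.775), or 3 lower and 2 higher with median-ratio scaling. Against Col-0-2, 9 were lower and 1 higher (median -1.26, adjusted p = 0.158). The lipoxygenase gene LOX2 (AT3G45140) averaged 4.80 ± 1.33 FPKM against 56.4 ± 11.1 and 17.01 ± 3.46. Wounding and touch genes were higher in 5 and lower in 4 of 9 against Col-0-1 (adjusted p = 0.245). TCH3 (AT2G41100) fell against both sets (log2 changes of -1.85 and -4.005), and ZAT12 (AT5G59820) rose against Col-0-1 (1.83) but not against Col-0-2 (-0.27, adjusted p = 0.251).

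The largest rises in dellaq that held against both sets, beside CRC and CRD, were AT1G04560 (0.630 ± 0.552 to 192 ± 83.1 FPKM, log2 changes of 6.84 and 6.99), AT2G05580 (0.271 ± 0.220 to 79.3 ± 31.6, 5.90 and 6.15) and the LEA family gene AT2G21490 (2.07 ± 1.78 to 154 ± 59.3, 5.72 and 6.59). They also included the plastid-encoded ATCG00470, whose change against Col-0-2 was far smaller (5.58 and 0.62). The largest falls, beside CA1, TGG2 and RBCS2B, were in the cell wall genes IRX15 (AT3G50220) (27.3 ± 1.94 to 0.746 ± 0.253 FPKM, -4.03 and -2.09) and LAC17 (AT5G60020) (20.3 ± 1.22 to 0.523 ± 0.0298, -3.81 and -1.68). Another was in AT2G19802 (131 ± 38.7 to 15.0 ± 18.5, -3.75 and -5.05). Adjusting over the lists alone moved few counts: in dellaq against Col-0-1, adjusted over the list alone, 2 mucilage genes were higher in place of 1, and 2 embryo patterning genes were higher and 6 lower in place of 3 and 7. For the other lists of this comparison the counts were the same. Against Col-0-2, camera called 9 lists in dellaq: upward seed regulators (adjusted p = 1.5e-04), storage proteins (3.9e-11), oil body genes (1.6e-10), fatty acid synthesis (7.6e-14), LEA genes (3.9e-11) and photosynthesis (1.4e-15), and downward flavonoids (2.3e-05), mucilage (0.00285) and cell cycle (4.2e-04). With an estimated correlation camera called 0 lists in dellaq against either set, and 3 lists had an unadjusted p under 0.05 against each. Against Col-0-2 adjusted p = 0.182 with an estimated correlation for seed regulators and fatty acid synthesis, the lowest, and 0.437 for mucilage, the highest among these lists.

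Seeds of lec1-4 had lower levels of plastid fatty acid synthesis genes and higher levels of some LEA genes than either wild-type set. Of 27 fatty acid synthesis genes, 22 were lower against both sets (24 with median-ratio or upper-quartile scaling, 15 with equal FPKM sums), as were 6 of 14 oil genes, and 6 of 19 LEA genes were higher. EMB3003 averaged 91.4 ± 2.41 FPKM in lec1-4 against 219 ± 4.86 in Col-0-2 and 201 ± 5.43 in Col-0-1 (log2 changes of -1.25 and -1.13, adjusted p = 8.2e-10 and 2.2e-08). The fatty acid elongase gene FAE1 (AT4G34520) averaged 7.76 ± 2.09 FPKM in lec1-4 against 33.4 ± 4.24 in Col-0-2 and 92.9 ± 15.6 in Col-0-1 (log2 changes of -1.996 and -3.44, adjusted p = 4.4e-07 and 4.2e-08). The beta-glucosidase gene PYK10 (AT3G09260), the main protein of endoplasmic reticulum bodies in seedlings, averaged 77.0 ± 7.32 FPKM in lec1-4 against 0.284 ± 0.173 in Col-0-2 and 0.385 ± 0.185 in Col-0-1 (log2 changes of 5.93 and 5.82, adjusted p = 3.7e-07 and 2.5e-06).

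Against Col-0-2, 13330 of 20222 genes differed in lec1-4, 8626 higher and 4704 lower, with 2218 changed by at least a log2 change of 1. Against Col-0-1 there were 5370 (3201 higher, 2169 lower). Calls held against both sets for 2466 genes, 1656 higher and 810 lower, with 1440 in opposite directions. The median change of all genes was 0.13 against Col-0-2 and 0.05 against Col-0-1. Median-ratio scaling moved the first to -0.01 and the held calls to 1030 higher and 1131 lower, upper-quartile scaling to 0.01 and to 1136 and 1056, and equal FPKM sums to 0.27 and to 2031 and 614. The excess of higher over lower calls thus turned with median-ratio scaling. Higher and lower calls against Col-0-2 were then 6009 and 6530, 6402 and 6188, and 11203 and 3507, and against Col-0-1 2402 and 2527 with median-ratio scaling.

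The fatty acid list was called downward (23 lower and 1 higher of 27, median -0.39, adjusted p = 1.5e-10, and adjusted p = 0.381 with an estimated correlation). Against Col-0-1 its call also held with an estimated correlation (adjusted p = 3.5e-32 and 0.0346). Among its members MOD1 (AT2G05990) averaged 219 ± 4.66 FPKM against 356 ± 11.7 and 351 ± 0.765 (log2 changes of -0.70 and -0.68). LTA2 (AT3G25860), another pyruvate dehydrogenase subunit, averaged 118 ± 7.58 against 240.3 ± 4.52 and 197 ± 10.7 (-1.02 and -0.74). Oil body and oil assembly genes were higher in 3 and lower in 6 of 14 cases (adjusted p = 0.0787; adjusted p = 0.0341 with equal FPKM sums). OLEO1 averaged 11.6 ± 7.19 FPKM in lec1-4 against 105 ± 21.4 in Col-0-2 and 765 ± 261 in Col-0-1 (log2 changes of -3.21 and -6.03, adjusted p = 5.8e-06 and 2.1e-07). ROD1 (AT3G15820), which moves diacylglycerol between membrane lipid and oil, averaged 17.3 ± 0.326 against 42.4 ± 4.72 and 59.1 ± 6.79 (log2 changes of -1.24 and -1.71). Storage protein genes were lower in 3 of 13 cases against Col-0-2 (median -0.60, adjusted p = 0.0787; adjusted p = 0.0187 with equal FPKM sums). They were lower in 12 of 13 against Col-0-1 (median -3.48, adjusted p = 1.6e-12, and adjusted p = 0.177 with an estimated correlation). The vicilin-like gene AT4G36700 averaged 165 ± 15.2 FPKM against 318 ± 12.8 and 354 ± 30.7 (log2 changes of -0.94 and -1.09). SESA1 (AT4G27140) averaged 5.72 ± 3.22 against 17.3 ± 1.31 and 99.9 ± 59.5 (-1.58 and -3.86, adjusted p = 0.0127 and 1.2e-04), a call against Col-0-2 lost without lec1-4 replicate 2 (-1.12, adjusted p = 0.0611).

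LEA and desiccation genes were higher in 12 and lower in 2 of 19 cases against Col-0-2, without a call for the list (median 0.89, adjusted p = 0.199). LEA7 averaged 41.5 ± 9.22 FPKM against 3.88 ± 1.39 and 14.0 ± 2.49 (log2 changes of 3.14 and 1.49), and LEA4-5 (AT5G06760) averaged 22.2 ± 12.2 against 0.671 ± 0.101 and 1.49 ± 0.778 (3.64 and 3.11). AT3G17520 averaged 12.9 ± 9.26 against 0.427 ± 0.155 and 0.518 ± 0.313. Seed regulators were higher in 10 and lower in 4 of 20 against Col-0-2 (adjusted p = 0.402), yet higher in 2 and lower in 11 against Col-0-1 (adjusted p = 6.9e-07, and adjusted p = 0.0348 with an estimated correlation). LEC2 was above both sets, at 28.3 ± 3.16 FPKM (log2 changes of 0.96 and 0.73, adjusted p = 9.5e-06 and 4.1e-04). FUS3, at 103 ± 6.93, was above Col-0-2 (1.17, adjusted p = 1.7e-07) and below Col-0-1 (-0.29, adjusted p = 0.0214). ABI3, at 30.4 ± 3.38, was below both (log2 changes of -0.26 and -1.44, adjusted p = 0.0136 and 2.0e-07). The call against Col-0-2 was lost without Col-0-2 replicate 3 (-0.20, adjusted p = 0.064), without lec1-4 replicate 2 (-0.17, adjusted p = 0.0637) and with equal FPKM sums (-0.11, adjusted p = 0.246).

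Stomata and trichome genes were higher in 11 of 12 cases against Col-0-2 (median 1.12, adjusted p = 0.0394, and adjusted p = 0.381 with an estimated correlation; adjusted p = 0.0768 with equal FPKM sums), but only 3 held against both sets. The stomatal lineage gene SPCH (AT5G53210) averaged 10.2 ± 1.301 FPKM against 1.52 ± 0.380 and 8.60 ± 0.996 (log2 changes of 2.16 and 0.22, adjusted p = 2.8e-08 and 0.207). The trichome regulator GL1 (AT3G27920) measured 2.89, 3.72, 6.36 FPKM in the lec1-4 libraries and was listed at 0 in the 6 wild-type libraries. Wounding and touch genes were lower in 9 of 9 cases (median -1.09, adjusted p = 0.0016, and adjusted p = 0.703 with an estimated correlation) but only 1 held against both sets. TCH3 averaged 29.8 ± 1.69 FPKM against 212 ± 37.5 and 46.2 ± 3.82 (log2 changes of -2.77 and -0.62, adjusted p = 7.6e-07 and 0.0716). Heat shock genes were lower in 5 of 7 (adjusted p = 0.0426, and adjusted p = 0.724 with an estimated correlation), and 4 held against both sets. The call ended with median-ratio (adjusted p = 0.122) and upper-quartile scaling (adjusted p = 0.0934). The chaperone gene HSP90.1 (AT5G52640) averaged 8.13 ± 0.314 FPKM against 15.2 ± 1.61 and 12.01 ± 1.398.

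Camera called no other list in lec1-4 against Col-0-2. Cell cycle genes were higher in 17 and lower in 1 of 25 cases (19 and 2 adjusted over the list alone, adjusted p = 0.0544; adjusted p = 0.0341 with equal FPKM sums), and 6 held against both sets, or 1 with median-ratio scaling. CDKB1;2 averaged 22.1 ± 0.815 FPKM (log2 changes of 0.30 and 0.35, adjusted p = 0.00222 and 0.00283). Photosynthesis genes were higher in 16 and lower in 12 of 42 (median 0.04, or -0.12 with median-ratio scaling, mean 0.14, camera downward, adjusted p = 0.876). Against Col-0-1, where plastid sums were 164 ± 31.8 in lec1-4 and 202 ± 42.9 FPKM in Col-0-1, 36 were lower (adjusted p = 4.9e-25, and adjusted p = 0.166 with an estimated correlation). LHCB6 averaged 246 ± 7.44 FPKM against 420.4 ± 21.8 and 399 ± 6.36. Endosperm markers were higher in 3 and lower in 7 of 14 (adjusted p = 0.0787; adjusted p = 0.0341 with equal FPKM sums). The sucrose transporter gene SUC5 (AT1G71890) fell to 54.1 ± 3.22 FPKM from 137 ± 6.81 and 83.6 ± 1.94. Mucilage genes were higher in 12 and lower in 7 of 24 (median 0.15, or -0.0016 with median-ratio scaling, camera downward, adjusted p = 0.921). Flavonoid genes were higher in 3 and lower in 5 of 15 (adjusted p = 0.231), and the lower count moved to 10 with median-ratio scaling, 9 with upper-quartile scaling and 2 with equal FPKM sums. Embryo patterning genes were higher in 10 and lower in 1 of 18 (adjusted p = 0.315), with the epidermal gene PDF1 (AT2G42840) at 592 ± 38.1 FPKM against 232 ± 19.7 and 409 ± 2.70 (log2 changes of 1.35 and 0.53). Silique wall markers were higher in 7 and lower in 1 of 10 (adjusted p = 0.199), and jasmonate and defence genes higher in 2 and lower in 4 of 12 (adjusted p = 0.199).

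Hormone lists in lec1-4 moved in both directions. Gibberellin synthesis and inactivation genes were higher in 6 and lower in 6 of 14 (median 0.05, or -0.08 with median-ratio scaling, camera downward, adjusted p = 0.658). Lower against both sets were 4, among them GA3OX3 (AT4G21690) (log2 changes of -1.08 and -0.82). DELLA-induced target genes were higher in 6 and lower in 4 of 12 (median 0.12, or -0.03 with median-ratio scaling, adjusted p = 0.916). Of 5 GASA genes 2 were higher and 1 lower (adjusted p = 0.876), with GASA4 at 76.1 ± 5.62 FPKM against 29.2 ± 3.52 and 22.8 ± 2.97 (log2 changes of 1.36 and 1.701, adjusted p = 7.4e-07 and 7.1e-07). Auxin genes were higher in 11 and lower in 6 of 18 (adjusted p = 0.876), with YUC10 lower against both sets (log2 changes of -0.87 and -1.14). Abscisic acid genes were higher in 12 and lower in 2 of 20 (adjusted p = 0.153), and NCED9 (AT1G78390), a dioxygenase gene of abscisic acid synthesis, rose (log2 changes of 1.97 and 0.33).

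The largest rises in lec1-4 that held against both sets, beside PYK10, were in the lipase gene LTL1 (AT3G04290) (0.820 ± 0.166 to 35.3 ± 4.59 FPKM, log2 changes of 4.32 and 4.36), AT2G15010 (1.08 ± 0.0519 to 41.3 ± 14.1, 4.29 and 3.19) and PBP1 (AT3G16420), which binds PYK10 (1.096 ± 0.265 to 37.1 ± 2.68, 4.19 and 4.61). Next came LEA76 (AT3G15670; 0.5004 ± 0.362 to 30.2 ± 21.2, 4.18 and 3.81) and AT1G52930, which differed little from Col-0-1 (3.97 and 0.40). The largest falls were in LEC1, AT3G24250 (332 ± 10.9 to 14.9 ± 0.970 FPKM, -4.39 and -2.82) and the plastid-encoded ATCG00220, ATCG00770, ATCG00800 and ATCG00810. The plastid genes followed the division of the libraries, with log2 changes against Col-0-1 of only -1.08, -0.67, -0.62 and -0.81. Against Col-0-1, camera called 9 lists in lec1-4. Beside those given above they were oil body genes (11 of 14 lower, adjusted p = 1.6e-12, and adjusted p = 0.123 with an estimated correlation), gibberellin synthesis and inactivation (7 of 14 lower, adjusted p = 0.0134, and adjusted p = 0.109 with an estimated correlation) and flavonoids (7 of 15 higher, adjusted p = 0.0153, and adjusted p = 0.551 with an estimated correlation). The others were cell cycle (10 higher and 1 lower, adjusted p = 0.0182, and adjusted p = 0.551 with an estimated correlation) and heat shock (4 lower, adjusted p = 0.0182, and adjusted p = 0.54 with an estimated correlation).

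Most genes called in both mutants changed in opposite directions, but among those held against both sets this was not so for changes of at least log2 1 (28 opposite, 29 in the same direction). A test of the difference between the changes passed for 15150 of 20222 genes (4476 with the higher change in dellaq, 10674 in lec1-4), or 12485 with the wild-type sets exchanged. Against the listed sets, 8535 genes passed in both mutants in opposite directions, against 5305 for independent lists, and 1710 in the same direction, against 4067 (r = -0.37 across genes, which are not independent replicates). These comparisons cross the division of the libraries in opposite ways. Genes that follow the division thus count as opposite and enter the 15150, and independent lists are no measure of chance for them. With the sets exchanged, each comparison within a side of the division, the counts were 3498 (1807) and 694 (1603), with r = -0.29. Among genes that held against both sets in each mutant, 1131 went in opposite directions and 356 in the same direction, against 549 and 392 for independent lists. Simulations without effects gave 0.2 and 0, but with each mutant set midway between the wild-type sets they do not measure differences between sets. Where the wild-type sets differ, few held calls could arise in them by construction. The comparisons against both sets share the wild-type libraries, whose chance values move the changes in both mutants the same way. Of the 1131, 817 were lower in dellaq and higher in lec1-4, and 314 the reverse, a split that depended on the setting. It was 1173 and 178 with equal FPKM sums, and it turned with median-ratio scaling (346 and 591), upper-quartile scaling (446 and 470), the length and GC trend removed (370 and 541) and for changes of at least log2 1 (3 and 25). The higher changes in dellaq and in lec1-4 by the test of the difference were 7148 and 6739 with median-ratio scaling, 6134 and 8007 with upper-quartile scaling, 3062 and 13382 with equal FPKM sums and 6672 and 6690 with the length and GC trend removed.

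EMB3003, MOD1, LHCB6, YUC10 and the vicilin-like gene AT4G36700 were higher in dellaq and lower in lec1-4 than in both wild-type sets, and LEC2 and CDKB1;2 lower in dellaq and higher in lec1-4. Higher in both mutants than in both sets were LEA7, AT3G02480 (156 ± 95.4 FPKM in dellaq and 70.5 ± 47.8 in lec1-4, against 4.05 ± 2.09 in Col-0-1 and 4.08 ± 0.957 in Col-0-2) and the lipid transfer protein gene LTP2 (AT2G38530) (1275 ± 279 and 369.6 ± 49.3, against 100.1 ± 47.0 and 31.1 ± 5.17), with AT2G15010 and LEA76. The genes with the largest opposite changes against the listed sets followed the division of the libraries instead. These were ATCG00220, ATCG00390, ATCG00780 and ATCG00790, higher in dellaq and lower in lec1-4, and AT3G41979, AT2G01020, AT1G52930 and MEE49 (AT4G01560), lower in dellaq and higher in lec1-4. MEE49 averaged 33.8 ± 1.01 FPKM in Col-0-1 and 38.9 ± 1.56 in lec1-4, against 1.59 ± 0.306 in Col-0-2 and 1.58 ± 0.371 in dellaq. The largest shared falls, in AT1G21395, AT1G59930, AT1G24212 and AT5G63230, did not hold for lec1-4 against Col-0-1, with AT1G21395 at 40.5 ± 5.31 FPKM in lec1-4 and 42.4 ± 15.6 in Col-0-1.

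**Figure D5:**
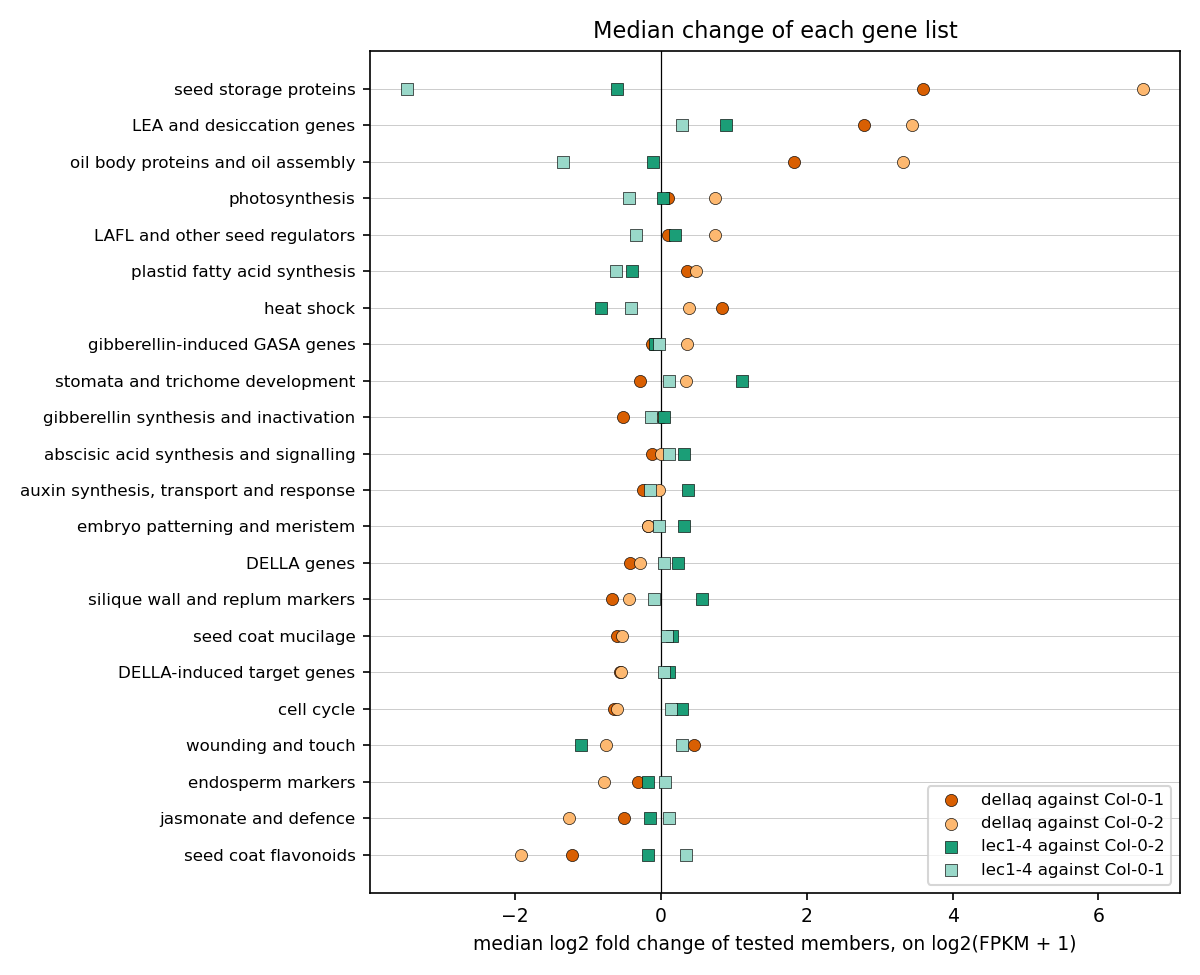
Median log2 change of each of the 22 gene lists in dellaq (circles) and lec1-4 (squares) against each wild-type set. Storage protein, oil and LEA lists lie furthest to the right in dellaq, and storage protein genes reach a median of -3.48 in lec1-4 against Col-0-1 and -0.60 against Col-0-2.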

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

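The test of the difference between the changes in the mutants was planned, while the regroupings of libraries were tested only after the result was seen.

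Several regulators changed differently in dellaq and in lec1-4, by a limma contrast of the log2 change in dellaq minus that in lec1-4, each against its listed wild-type set. The differences were -0.52 for RGA (adjusted p = 2.7e-05), -3.30 for RGL1 (7.1e-10), -3.00 for RGL2 (7.4e-09), 4.74 for LEC1 (1.8e-07), 0.44 for ABI3 (0.0043), -1.08 for FUS3 (3.5e-06) and -2.58 for LEC2 (2.1e-08). With the wild-type sets exchanged they were -0.26 for RGA (0.00752), -2.13 for RGL1 (7.6e-08), -1.85 for RGL2 (1.0e-06), 3.49 for LEC1 (5.6e-06), 2.804 for ABI3 (4.0e-09), 1.84 for FUS3 (8.0e-08) and -2.12 for LEC2 (2.6e-07). The direction for FUS3 thus turned with the choice of wild-type set, and those for the other 6 genes did not. The genes shown were kept because they passed this contrast with both choices. GAI and RGL3, also named by the rule, did not pass with both and are left out. The differences for LEC1, RGL1, RGL2 and RGA largely restate their lower levels in lec1-4 or dellaq given above and are no separate finding.

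Over all tested genes, the changes differed for 15150 genes with the listed sets and 12485 with the sets exchanged. The listed comparisons cross the division of the libraries in opposite ways, so genes that follow it enter the 15150. Among 100 drawn regroupings of the 12 libraries, only the real grouping, 1 of 100, gave as many as 15150, and the highest other gave 495. A regrouping mixes groups whose libraries lie close together, which raises the spread within its groups, so whether chance can be excluded is not concluded from it. The groups also differ in library features, which a regrouping cannot separate from genotype.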

How the results depend on the processing

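The scalings, the removal of plastid, mitochondrial and rRNA genes, and the removal of the length and GC trend were tested only after the results were seen; the other settings were planned. Apart from the DELLA genes, LEC1, FUS3, ABI3 and LEC2, the genes counted here were named for large changes or small p in this same fit. Their stability therefore says little about the other calls. Of 158 results for named genes, all kept their direction and side of the threshold with no low-value filter and with a pseudocount of 0.1, 157 with only the compared libraries, and all 153 that could be computed with the 5 FPKM filter or without organelle and rRNA genes. With median-ratio scaling 154 did (1 weaker, 3 newly past the threshold), with upper-quartile scaling 155, with equal FPKM sums 155, with the mean of both wild-type sets 152, and with the length and GC trend removed 149 of 153. Leaving out lec1-4 replicate 2 left 153 so and each other library 156 to 158. The other wild-type set moved most: 118 were the same, 16 weaker, 3 newly past the threshold and 21 reversed. Reversed means that the sign of a called change turned, whether or not it passed the threshold in the new direction.

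With the other wild-type set, 5370 genes changed in lec1-4 with 9 lists called, and 3498 and 694 genes were called in both mutants in opposite and the same directions. With the mean of both sets these were 8 lists and 5649 opposite genes. Log2 changes that reversed with the other set were, in dellaq, GA3OX1 0.89, GASA6 0.39, NCED9 0.41, SCR 0.60, ZAT12 -0.27 and ERF104 -0.57. In lec1-4 they were FUS3 -0.29, GA3OX1 -0.52, GA2 -0.044, GA20OX2 0.17, GASA6 -0.022, IAA2 -0.21, TT2 0.42, ICE1 0.075, SCR -0.063, PDF2 -0.16, FIL -0.10, CYCA2;3 -0.18, PR2 0.12, LOX2 -0.058 and ZAT12 0.30. Only GA3OX1, GASA6, NCED9 and SCR in dellaq and FUS3, GA3OX1, TT2 and PDF2 in lec1-4 passed the threshold in the new direction. The rest lost their call without a call in the new direction, as did GASA6 in lec1-4 (adjusted p = 0.917). SCR in dellaq also reversed with the mean of both sets (0.15, adjusted p = 0.0249). With the length and GC trend removed its sign turned without passing (0.0069, adjusted p = 0.927). The cause was not tested for these.

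A limit of log2 1 left, by its construction, 2329 genes in dellaq, 2218 in lec1-4, 2299 between the wild-type sets and 5774 whose changes differ. It left 739 and 245 genes called in both mutants in opposite and the same directions, 1193 and 221 held against both sets in dellaq and lec1-4, and 28 and 29 held in both mutants in opposite and the same directions.

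Gene lists called were 10 in dellaq and 4 in lec1-4. Camera with an estimated correlation called 0 and 0, with 3 and 2 lists at an unadjusted p under 0.05, and fry called 19 and 15. In lec1-4 there were 2 with the 5 FPKM filter, 7 with equal FPKM sums and 3 to 7 when leaving out a library (7 without lec1-4 replicate 3), and the cause was not tested. In dellaq there were 10 without each library in turn. Of 6 tests of the DELLA genes and LEC1 in their own mutants 4 passed, or 5 without dellaq replicate 2 or lec1-4 replicate 2, when RGL3 also passed.

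Leaving out each library gave 13182 to 14193 genes in dellaq, 12430 to 13482 in lec1-4, 12285 to 13481 between the wild-type sets, 14654 to 15025 whose changes differ, 8009 to 8338 opposite and 1510 to 1779 in the same direction. Held against both sets were 6818 to 7650 in dellaq and 1910 to 2627 in lec1-4, and in both mutants 855 to 1199 opposite and 256 to 407 in the same direction.

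In no mutant and wild-type set compared did every pair of same-numbered libraries correlate over 0.1 in its deviations across genes, so the numbers were not taken as pairs. Same-numbered libraries correlated at -0.10 to 0.19 and others at -0.14 to 0.16. Between Col-0-1 and lec1-4, which were not blocked together, same-numbered libraries correlated at 0.030, 0.19 and 0.076. The storage protein genes' mean deviation from the group mean was 0.153, -0.990, 0.837 by replicate in Col-0-1 and 0.141, -0.855, 0.714 in lec1-4. A replicate structure shared by these groups was therefore not excluded. With the replicate block of the listed sets, 13786, 12990 and 10277 genes changed in dellaq, in lec1-4 and between the wild-type sets, 14889 changes differed, and 8195 and 1640 genes went in opposite and the same directions. Held counts were 5748 in dellaq, 1115 in lec1-4, and 466 (243 lower and 223 higher in dellaq) and 170 in both mutants in opposite and the same directions, with 10 and 5 lists called. RGL3 and ABI3 in dellaq passed with the block (adjusted p = 0.0385 and 0.0419), and no other named call changed.

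The planned count tests and their size factors were not run because the values are FPKM. Without counts, depth limits are known only from the estimated 13.7 M to 19.4 M fragments per library, and low genes rest on few fragments.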

Other observations

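The genes outside the lists named here were chosen after their values were seen, and the tests of explanations and the splits of libraries were chosen only after the results were seen.

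Beside PYK10 and PBP1, other single genes were higher in lec1-4 than in both wild-type sets, and no list of such genes was tested. NAI2 (AT3G15950), needed to form endoplasmic reticulum bodies, averaged 18.5 ± 2.52 FPKM in lec1-4 against 0.595 ± 0.194 in Col-0-2 and 0.320 ± 0.0454 in Col-0-1 (limma log2 changes of 3.61 and 3.88, adjusted p = 2.4e-06 and 7.9e-06). The lectin gene JAL34 (AT3G16460) averaged 10.4 ± 0.903 against 0.797 ± 0.112 and 0.278 ± 0.0994 (2.67 and 3.16). In dellaq, PYK10 spread over 2.78, 21.01, 4.94 FPKM by library and NAI2 over 0.626, 4.35, 0.650, in both cases highest in replicate 2. Lower in lec1-4 were the carboxypeptidase-like gene scpl17 (AT3G12203) (1.82 ± 0.685 FPKM against 13.2 ± 2.14 and 81.9 ± 23.9), the expansin gene EXPA5 (AT3G29030) (5.00 ± 0.497 against 27.9 ± 2.398 and 57.0 ± 5.91) and AT2G34700 (167 ± 13.7 against 542 ± 35.01 and 735 ± 40.0). EXPA5 and AT2G34700 averaged 143 ± 4.75 and 1284 ± 50.0 FPKM in dellaq.

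Single genes outside the lists also stood above both wild-type sets in dellaq. The seed vacuole aquaporin gene TIP3;1 (AT1G73190) averaged 83.9 ± 30.5 FPKM against 2.53 ± 2.03 and 0.302 ± 0.183 (limma log2 changes of 4.67 and 5.97, adjusted p = 4.0e-07 and 5.2e-08), and the ketoacyl synthase gene KCS16 (AT4G34250) 38.5 ± 11.2 against 0.802 ± 0.151 and 0.535 ± 0.282. Lower were the proline-rich protein gene PRP2 (AT2G21140) (1.41 ± 0.539 FPKM against 24.5 ± 4.51 and 22.8 ± 1.02, log2 changes of -3.41 and -3.33) and ECS1 (AT1G31580) (6.87 ± 4.95 against 60.8 ± 12.9 and 60.9 ± 7.99, -3.13 and -3.14).

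Col-0-2 and dellaq libraries stood apart from Col-0-1 and lec1-4 libraries in organelle transcripts, rRNA loci and the trend with gene length. Against more photosynthetic tissue as the cause between the wild-type sets, nuclear photosynthesis genes had a median log2 change of -0.60 in Col-0-2 against Col-0-1 while plastid-encoded genes had one of 1.43. This does not extend to dellaq against Col-0-2, where both rose. There 36 of 42 nuclear photosynthesis genes were higher and 5 lower (median 0.75), and 75 of 99 plastid-encoded genes were higher (median 1.27). The nuclear median in dellaq against Col-0-1 was 0.10. Against the length and GC trend as the whole cause, 12500 genes still differed between the wild-type sets after its removal. Less complete poly-A selection would raise organelle and rRNA transcripts together. Mitochondrial genes did rise with the plastid ones (median 1.11), though summed FPKM went from 85.0 to 195 for them and from 202 to 4819 for plastid genes. The summed rRNA loci were lower in each Col-0-2 library than in each Col-0-1 library (log2 ratio -4.32). This argues against less complete selection as a single cause of both features, and for the organelle transcripts alone it stays open. A difference in seed stage between the sets stays open, since the correlation with storage protein slopes given for dellaq in the next paragraph was -0.52 for Col-0-2 against Col-0-1 (two-sided exact permutation p = 0.0162), while a difference in harvest was not tested, and for each mutant against its listed set the library side and the genotype change together.

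Storage protein, oil body and LEA genes were higher in dellaq. Against the library features that dellaq shares with Col-0-2 as the cause, 44 of 46 members were higher than in Col-0-2 and 43 than in both sets. These calls were seen before the explanation was weighed, so they restate the pattern and are no separate test. The likeness to Col-0-2 was also incomplete, since 75 of 99 plastid genes were still higher in dellaq than in Col-0-2. The dellaq libraries correlated less with those of Col-0-2 (mean r 0.896 across genes) than of Col-0-1 (0.914). A candidate explanation is that dellaq seeds were further along in maturation when sampled. Of 19869 genes outside the lists, 522 were selected because their within-group deviations correlated with the storage protein score beyond 0.8 in size. Across these 522, each gene's slope on that score correlated with its change in dellaq against Col-0-2 at r = 0.81 (two-sided exact permutation p = 0.00154 over 1296 within-group orders, highest permuted r 0.812). Against Col-0-1 it did so at 0.80 (p = 0.000772, the smallest these exact permutations can give). When the score used no dellaq library, the selection gave another 1207 genes, with r = 0.69 and 0.65. Over all 19869 genes r was 0.37 and 0.32. That dellaq seeds were further along remains a hypothesis. A later stage and an effect of the genotype on maturation genes would give the same values, and the samples hold a single time point. In lec1-4 the correlations were 0.31 against Col-0-2 and -0.28 against Col-0-1 (two-sided exact permutation p = 0.127 and 0.118). These exact permutations reordered each group separately, so their p-values assume that no replicate structure is shared between groups.

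Cell cycle and seed coat genes were lower in dellaq. Against a few abundant transcripts taking more of the FPKM total as the whole cause, 40 of 64 members were lower than in both sets with median-ratio scaling, against 52 as deposited. For a smaller share of seed coat as the whole cause the tables do not decide. The median change of mucilage genes lay 1.39 above that of flavonoid genes against Col-0-2 (permutation p = 0.0017, 10000 permutations of genes between the lists). It lay 0.61 above it against Col-0-1 (permutation p = 0.0273). The lists also lay apart between the wild-type sets (-0.56, permutation p = 0.0718), and how specific each is to the seed coat was not measured. These p-values treat genes as independent and do not measure the spread between libraries. By the first criterion, p below 0.05 against both sets, a smaller share of seed coat was excluded. The comparison with the wild-type difference was added to the criterion after these values were seen, and it turned that verdict. A change within seed coat development, or an earlier end of cell division with a later stage, may contribute and was not tested.

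For the comparisons of 3 against 3 libraries, the 10 possible splits are too few for a share under 0.05. The real count and the highest of the other splits were 14218 and 0 genes for dellaq against Col-0-1, 12843 and 1 against Col-0-2, 13330 and 0 for lec1-4 against Col-0-2, 5370 and 2 against Col-0-1, and 13320 and 0 between the wild-type sets. For gene lists called they were 10 and 12 for dellaq against Col-0-1, 9 and 11 against Col-0-2, 4 and 10 for lec1-4 against Col-0-2, and 9 and 9 against Col-0-1; 2, 7, 8 and 2 of the 10 splits, the real ones included, called as many lists.

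Among 100 drawn regroupings, only 1, the real one, gave any genes called in both mutants, in opposite (8535, highest other 0) or the same direction (1710, 0), or against both sets in opposite (1131, 0) or the same direction (356, 0). The same-direction counts lay below those of independent lists (4067 and 392). The 7716 genes of dellaq held against both sets were reached by 1 of 100 regroupings, the real one, and the highest other, 5707, kept the dellaq libraries together and mixed the wild-type sets. For the 2466 genes of lec1-4 held against both sets, 5 of 100 were as large, and the highest, 10146, set the Col-0-2 libraries against mixtures of Col-0-1 and lec1-4, which points to the structure of the samples. Because a regrouping either mixes groups whose libraries lie close together, which raises the spread within its groups, or keeps a real group whole, whether chance can be excluded is not concluded from any of these counts.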
